A study of Arabidopsis thaliana with 6 samples.

How the data were processed

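Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Arabidopsis thaliana inflorescences, about 1 g of tissue per sample, from plants grown at 22 °C with 16 h of light and 8 h of dark per day, per the labels' protocols. The plants were rescue lines of the sep1,2,3 background that carried either wild-type SEP3 (SEP3wt) or a SEP3 unable to form tetramers (SEP3tet). Per the labels, each line gave 2 ChIP samples with a native SEP3 antibody and 1 mock sample with pre-immune serum, 6 samples in all. Precipitation used protein A beads and libraries were made with a ThruPLEX kit, per the labels' protocols.

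The deposited values were 2 peak lists, 1 per line, each named in the labels of both ChIP samples of that line. Per the submitters' processing notes, the tools were Trimmomatic 0.36, Bowtie2 2.2.5, MACS2 2.2.7.1 and deepTools, and the genome build was TAIR10. How the 2 replicates of a line were combined, and whether the mock library served as the control, is not given in the sources used here. Each peak has a start, an end, a summit, a fold enrichment, a −log10 p, a −log10 q and a display score. The fold enrichment is the authors' ratio of ChIP signal to the peak caller's background at the summit, taken to be so from the narrowPeak layout that MACS2 writes. The −log10 p and −log10 q values are those of the authors' peak caller, and the lowest −log10 q of the lists corresponds to a q near 0.05. The deposited score equalled the whole part of 10 times the −log10 q in every peak and was not used further, nor was the −log10 p. Every fold and q printed is the authors' own value and was used to describe, rank or filter peaks within 1 list; where peak numbers were compared at a stricter q, the same threshold filtered each list.

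Gene names and gene neighbourhoods came from a RefSeq gene table of assembly TAIR10.1 with 27444 protein-coding nuclear genes. Coordinates printed are those of the peaks on TAIR10, counted from 1, and none come from the gene table. To test whether the positions of both builds could be used together, all summits were shifted by 10 distances of 1 to 20 kb in either direction. The share of summits in gene bodies was 45.3% (SEP3wt) and 39.8% (SEP3tet) without a shift, against 54.7 to 64.0% and 54.3 to 64.0% with one. It was lowest without a shift on 5 of 5 chromosomes in both lines. The gene table gives no strand, exons or UTRs and no genome sequence was used here. The planned window of 3 kb upstream to 1 kb downstream was therefore replaced by 3 kb to either side of the gene, the nearest gene start by the nearest gene edge, and the split into exons, introns and UTRs by gene body, within 1 kb, 1 to 3 kb and beyond 3 kb of a protein-coding gene. The planned counts of CArG boxes, CArG box pairs and other motifs under the peaks were not made. Where pericentromeric regions were to be left out, 500-kb windows poor in genes were left out in their place.

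Peaks were called shared where they overlapped a peak of the other line by at least 1 bp. Random placement used 1000 draws on the same chromosome, one-sided, and a further 1000 that placed peaks at random genes. Fold enrichment of shared and line-only peaks was compared within each list by a two-sided permutation test with 100000 resamples, adjusted by the Benjamini-Hochberg method. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error over peaks or genes only. Locations were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 5 such tests. A gene was a target of a line where a summit lay in the gene or within 3 kb of it, so that a summit can belong to several genes. For several targets named below the strongest peak lay nearest to a neighbouring gene, among them PI, SOC1, FD, FLC, RBE, YUC4 and DYT1. Lists of genes were tested among targets against all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 23 lists and 2 lines. These were 8 lists of 165 genes in all, each matched by its locus, and 15 families defined by gene symbol, all fixed before the data were examined, as were the tests and the alternatives except where stated otherwise. The result of 1 of the 15 families is not reported here. A further 4 families were added after the peaks were seen and adjusted apart.

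The genes named were set by a rule fixed before the data were examined. Named are every member of the floral organ identity list, up to 8 targets of either line per other list in list order, and the 8 peaks with the highest fold among shared (ranked in SEP3wt), SEP3wt-only and SEP3tet-only peaks with a summit in the window of a gene with a symbol. Genes named outside this rule are said to be so where they appear, apart from neighbours named to place a peak and the genes of the widest peaks.

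No values per replicate were held, so replicates were not compared, no replicate was left out, and no test spans plants. The p-values describe peaks or genes of these lists, which are not independent replicates, and not the spread between plants. Library sizes are unknown here, and signal of the mock samples was not analysed here. The overlap and gene list steps were tested on simulated data. All planted shared peaks were found (100%), an outcome fixed in advance because they were exact copies of SEP3wt peaks. Among 200 random lists of 20 genes drawn from 27444 for the SEP3tet targets, 100% were called when 10 of the 20 genes were given a summit. Without planted summits 2.5% were called. Smaller lists and weaker effects were not simulated. Alternatives covered stricter q thresholds of −log10 q of at least 5 and 10, a reciprocal overlap of at least 50%, summits within 100 bp, equal numbers of strongest peaks, narrower windows, the nearest gene only, and 10000 random lists matched on non-coding bases. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.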

Results

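SEPALLATA3 (SEP3) is a MADS-domain transcription factor that acts with AP1, AP3, PI and AG in floral organ identity and forms dimers and tetramers with its partners. Its binding was mapped by ChIP-seq with a native SEP3 antibody in inflorescences of 2 rescue lines of the sep1,2,3 background, 1 with wild-type SEP3 (SEP3wt) and 1 with a tetramerization-deficient SEP3 (SEP3tet). Each line had 2 ChIP samples and 1 pre-immune mock. The data compared were 1 peak list per line, and the comparison asks which regions and genes SEP3 occupies with and without tetramerization. Sequencing depth is unknown here, signal of the mock samples was not analysed here, and with 1 list per line no difference between the lines could be set against the spread between replicates.

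More peaks were called for the tetramerization-deficient protein than for the wild-type protein, in lists of mostly narrow peaks spread over all 5 chromosomes. The SEP3tet list held 3601 peaks and the SEP3wt list 2225, a ratio of 1.62. Peaks covered 1344 kb in SEP3tet and 901 kb in SEP3wt, a ratio of 1.49. The median width was 282 bp (137 to 5102 bp) in SEP3tet and 262 bp (120 to 5224 bp) in SEP3wt. Chromosome 1 held 27.2% of SEP3tet and 27.5% of SEP3wt peaks, beside 26.1% of protein-coding genes. The authors' fold enrichment ran from 1.97 to 11.9 in the SEP3tet list and from 1.98 to 10.8 in the SEP3wt list, with −log10 q from 1.40 to 57.6 and from 1.32 to 60.0. At a −log10 q of at least 10 the numbers fell to 1114 and 626.

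Most peaks of wild-type SEP3 overlapped a SEP3tet peak, among them strong peaks at IAA4, LOG1, SRC2, CBF2 and TOE3. In SEP3wt, 1884 of 2225 peaks (84.7%, 95% interval 83.1 to 86.1) overlapped a SEP3tet peak, and in SEP3tet 1921 of 3601 (53.3%, 51.7 to 55.0) overlapped a SEP3wt peak. The remaining 341 SEP3wt-only and 1680 SEP3tet-only peaks had no overlap. Of shared peaks whose nearest gene lay within 3 kb of the summit and had a symbol, the 8 with the highest fold in the SEP3wt list lay at ATAUX2-11 (IAA4), an auxin-inducible Aux/IAA gene, at LOG1, a cytokinin-activating enzyme, and at SRC2, OZF2, CBF2, AGC1.7, TOE3 and SPL8. The SRC2 and CBF2 peaks were wide, at 1908 and 1489 bp in SEP3wt, with summits in the gene body. The AGC1.7 peak spanned 5224 bp. The IAA4 peak (AT5G43700; chromosome 5, 17549899 to 17550528; summit in the gene body) had a fold of 10.5. The LOG1 peak (AT2G28305; chromosome 2, 12078285 to 12078780; 1 to 3 kb from the gene) had a fold of 10.2. At TOE3, which encodes an AP2-like floral repressor (AT5G67180; chromosome 5, 26805341 to 26805909; 1 to 3 kb from the gene), the fold was 9.24.

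The overlap lay far above random placement, which gave 2.29% ± 0.314 (SD over 1000 draws) of SEP3wt and 1.41% ± 0.194 of SEP3tet peaks, permutation p = 0.000999, one-sided, the smallest the draws can give. Placement at random genes gave 2.69% and 1.77%. Over 1726 pairs of peaks that overlapped only each other, summits lay a median of 25 bp apart, and 87.7% lay within 100 bp. Requiring summits within 100 bp lowered the shared share to 71.2% of SEP3wt and 44.0% of SEP3tet peaks.

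Peaks found in 1 line alone were the weaker ones of their own list. The SEP3wt-only peak with the highest fold (7.58, −log10 q 32.8) was an exception; it lay 1 to 3 kb from LEJ2, a neighbour of the organ identity gene AP2 (AT4G36910; chromosome 4, 17395482 to 17396090). It was followed by peaks in the bodies of LHCB2.1 and CAB2, which encode light-harvesting chlorophyll-binding proteins, then PHI-1, BXL1, ARF8, VSP1 and LHCB2.3, with folds from 5.01 (LHCB2.1, chromosome 2, 1823154 to 1824296) to 3.70 (LHCB2.3, chromosome 3, 10256302 to 10256915). CAB2 also had 2 SEP3tet summits in the gene or within 3 kb. The strongest SEP3tet-only peaks lay at DEAR2, a neighbour of TOE3 (AT5G67190; chromosome 5, 26806731 to 26807094; fold 6.64), and at SSL1, CHIP, TT16, LDL2, HDG1, RBP47A and HR1. TT16 encodes a MADS-domain protein of seed coat development; its SEP3tet-only peak (AT5G23260; chromosome 5, 7835211 to 7835518) had a fold of 6.11 and lay within 1 kb of the gene, which also had 1 summit in SEP3wt.

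In the SEP3wt list the median fold was 3.56 for shared and 2.83 for SEP3wt-only peaks (permutation test, adjusted p = 1e-05, the smallest 100000 resamples can give). In the SEP3tet list it was 4.37 for shared and 3.22 for SEP3tet-only peaks (same test and p). With each list split by fold into 5 parts, the shared share in SEP3wt rose from 60.7% in the lowest part to 99.1% in the highest. In SEP3tet it was 34.3%, 28.2%, 45.6%, 66.0% and 92.8% from the lowest part to the highest. Among line-only peaks, 105 SEP3wt-only (30.8%) and 197 SEP3tet-only (11.7%) had a peak of the other line within 1 kb.

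**Figure D1:**
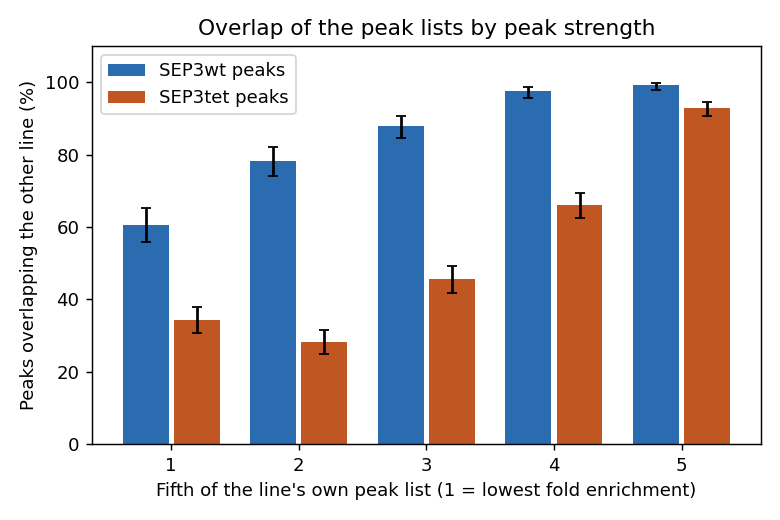
Share of peaks (%) that overlap the other line's list, for SEP3wt (blue) and SEP3tet (orange), in 5 parts of each line's own list ordered by the authors' fold enrichment; error bars are exact 95% intervals over peaks. The share reaches 99.1% of SEP3wt and 92.8% of SEP3tet peaks in the highest part.

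SEP3 peaks of both lines gathered next to genes, while peaks found only with wild-type SEP3 lay mostly inside gene bodies. Of SEP3wt summits, 36.9% lay outside genes but within 1 kb of a protein-coding gene, and of SEP3tet summits 41.3%, beside 20.4% of genome bases. Gene bodies held 45.3% of SEP3wt and 39.8% of SEP3tet summits, beside 54.1% of genome bases, and only 2.52% and 2.50% of summits lay beyond 3 kb, beside 14.3% of bases. Of SEP3wt-only summits, 227 of 341 (66.6%, 61.3 to 71.6) lay in gene bodies, against 635 of 1680 SEP3tet-only summits (37.8%, 35.5 to 40.2). Nuclear photosynthesis genes held 12 of the 227 SEP3wt-only gene-body summits and 1 of the 635 SEP3tet-only ones. This family was chosen because such genes were seen among the SEP3wt-only peaks, so the contrast decides nothing.

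The odds ratio of SEP3wt-only against SEP3tet-only peaks for gene bodies was 3.28 (Fisher's exact test, p = 2.64e-22, adjusted p = 1.32e-21). Against the shared SEP3wt peaks, of which 41.5% lay in gene bodies, the adjusted p was 2.77e-17. SEP3tet-only and shared SEP3tet peaks lay closer together, at 37.8% and 41.5% (Fisher's exact test, adjusted p = 0.0223). Wide peaks were mostly in genes: of peaks over 1 kb, 92.0% of 174 in SEP3wt and 86.8% of 136 in SEP3tet had their summit in a gene body, against 41.3% and 38.0% of narrower ones (Fisher's exact p = 5.76e-42 and 9.46e-31). Most of these wide peaks were shared, 97.1% in SEP3wt and 98.5% in SEP3tet. UBQ10, named after its value was seen, held a shared one (SEP3wt, chromosome 4, 2718243 to 2720498, fold 7.87). Whether shared wide peaks hold background over genes was not tested. With only line-only peaks of −log10 q of at least 10, the difference between SEP3wt-only and SEP3tet-only peaks was 27.3 percentage points with a Fisher's exact p of 0.205.

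**Figure D2:**
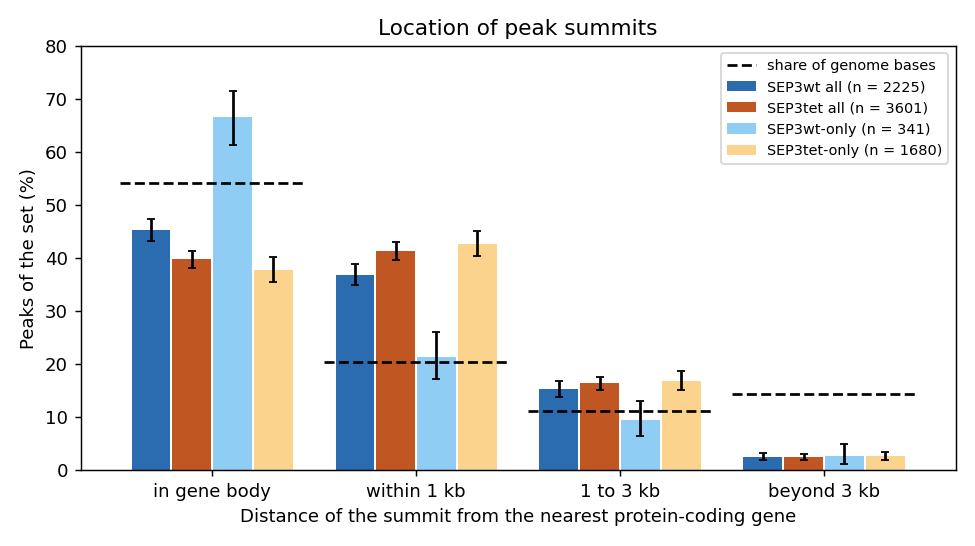
Share of summits (%) in gene bodies, within 1 kb, 1 to 3 kb and beyond 3 kb of protein-coding genes, for all SEP3wt (2225), all SEP3tet (3601), SEP3wt-only (341) and SEP3tet-only (1680) peaks; error bars are exact 95% intervals over peaks and dashed lines the share of genome bases. SEP3wt-only peaks stand at 66.6% in gene bodies, above the 54.1% of genome bases, and SEP3tet-only peaks at 37.8%, below it.

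The floral organ identity genes were targets of wild-type SEP3 and of SEP3tet alike. Of 14 genes, 10 had a summit in the gene or within 3 kb in both lines: AP1, FUL, AP2, AP3, PI, AG, SEP3, SEP4, SHP1 and SHP2. SEP1 was a target in SEP3wt only, SEP2 in SEP3tet only, and CAL and STK in neither. The odds of being a target against all other genes were raised 23.2 times in SEP3wt (11 of 14; adjusted p = 3.52e-06) and 13.7 times in SEP3tet (11 of 14; adjusted p = 0.000112, Fisher's exact test).

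AP1 (AT1G69120), which specifies sepals and petals, had 3 summits in each line, the strongest in SEP3wt 1 to 3 kb from the gene (chromosome 1, 25987694 to 25988173; fold 6.42). AP2 (AT4G36920) had 4 summits in SEP3wt, the strongest at 17398748 to 17399160 of chromosome 4 (fold 7.72, 1 to 3 kb from the gene), and 3 in SEP3tet. FUL (AT5G60910), a regulator of fruit and meristem, had 1 summit in SEP3wt and 3 in SEP3tet. AP3 (AT3G54340), a petal and stamen identity gene, had 1 in each, in the gene body (SEP3wt, chromosome 3, 20121114 to 20121371; fold 4.63). The single PI peak of each line had its summit in the body of the neighbouring gene BCB (SEP3wt, chromosome 5, 6826530 to 6827472; fold 4.01). AG (AT4G18960), which specifies stamens and carpels, had 3 summits in SEP3wt and 2 in SEP3tet, the strongest in SEP3wt at 10381018 to 10381469 of chromosome 4 (fold 7.99, 1 to 3 kb from the gene).

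SHP2 (AT2G42830), a fruit valve margin gene, had its strongest peak within 1 kb (SEP3tet, chromosome 2, 17819612 to 17820230; fold 9.77), and SHP1 (AT3G58780) inside the gene (SEP3tet, chromosome 3, 21737920 to 21738619; fold 9.38). SEP4 (AT2G03710) had 1 summit in each line, within 1 kb. The peaks that set SEP1 and SEP2 apart were weak: fold 3.27 and −log10 q 4.95 at SEP1 in SEP3wt (AT5G15800; chromosome 5, 5154430 to 5154576), and fold 3.07 and −log10 q 3.62 at SEP2 in SEP3tet (AT3G02310; chromosome 3, 467766 to 467983). SEP3 itself (AT1G24260) had 3 summits in each line, the strongest nearest to the neighbour AT1G24265 (SEP3tet, chromosome 1, 8598301 to 8599229; fold 7.70), and reads of the transgene and the native copy were not told apart here.

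Over all 27444 protein-coding genes, 3759 (13.7%) were targets in SEP3wt and 5814 (21.2%) in SEP3tet. Both lines shared 3401, against 796 for independent lists of these sizes; this was 90.5% of SEP3wt and 58.5% of SEP3tet targets. SEP3wt alone had 358 and SEP3tet alone 2413, which became 868 and 1125 with equal numbers of strongest peaks in both lists. Counting only the nearest gene of each summit gave 1833 targets in SEP3wt, 2883 in SEP3tet and 1620 in both. Of 23 lists tested, 8 were over-represented in SEP3wt and 9 in SEP3tet, and none was under-represented. The share of list members did not differ between SEP3wt-only and SEP3tet-only targets for any of the 23 lists after adjustment (0 passed), a test that small lists with mostly SEP3tet-only members could not pass, since most line-only targets were SEP3tet-only.

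Flowering regulators were over-represented in both lines, with 13 of 22 genes in SEP3wt (odds ratio 9.13, adjusted p = 1.99e-05) and 14 of 22 in SEP3tet (odds ratio 6.52, adjusted p = 0.000193, Fisher's exact test). Targets of both lines included SOC1, a promoter of flowering, SVP, a repressor, FD, which partners with FT, AGL15, AGL18 and SPL9. AGL15 (AT5G13790) had a fold of 8.97 in SEP3wt (chromosome 5, 4450681 to 4451315; within 1 kb) and AGL18 (AT3G57390) one of 8.64 (chromosome 3, 21233393 to 21233874; gene body). FLC, a repressor of flowering, and LFY, which specifies floral meristems, were targets in SEP3tet only, with folds of 2.83 and 3.36. Organ growth and polarity genes had 9 of 24 targets in SEP3wt (odds ratio 3.79, adjusted p = 0.00903) and 14 of 24 in SEP3tet (odds ratio 5.22, adjusted p = 0.000408, Fisher's exact test), and passed in neither with gene bodies alone (adjusted p = 0.719 and 0.266). JAG, which promotes petal growth, the leaf polarity genes PHB and PHV, RBE and TCP4 were targets in both lines. BOP1, BOP2 and PTL were targets in SEP3tet only, with folds of 4.42 (BOP1; chromosome 3, 21144747 to 21145145), 4.13 (BOP2; chromosome 2, 17242363 to 17242911) and 2.59.

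Hormone pathway genes had 12 of 27 targets in SEP3wt (odds ratio 5.05, adjusted p = 0.000461) and 14 of 27 in SEP3tet (odds ratio 4.01, adjusted p = 0.00151, Fisher's exact test). The auxin transport genes PIN3, PIN4 and PIN7, the kinase gene PID, the auxin receptor gene TIR1 and ARF6 were targets in both lines, PIN3 with a fold of 7.34 in SEP3wt (AT1G70940; chromosome 1, 26744717 to 26745322; gene body). ARF8, which acts with ARF6 in stamen and petal growth, was a target in SEP3wt only (AT5G37020; chromosome 5, 14630391 to 14630586; gene body; fold 3.92), and the auxin synthesis gene YUC4 in SEP3tet only (fold 5.10). In SEP3tet the hormone list no longer passed with a window of 1 kb (7 targets, exact test, adjusted p = 0.0905) or with gene bodies alone (4 targets, 0.122).

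Stamen and pollen genes had 3 of 13 targets in SEP3wt (odds ratio 1.89, adjusted p = 0.494) and 7 of 13 in SEP3tet (odds ratio 4.34, adjusted p = 0.0263, Fisher's exact test). EMS1 and MYB21 were targets in both lines, MS1 in SEP3wt only, and SPL/NZZ, DYT1, TPD1, ROXY1 and DAD1 in SEP3tet only, DYT1 with a fold of 4.47 (chromosome 4, 11352086 to 11352368). The strongest peaks counted for SPL/NZZ, DYT1, TPD1, ROXY1, MS1 and EMS1 lay nearest to a neighbouring gene. Those of DAD1 and MYB21 lay nearest to these genes themselves. The SEP3tet result was lost in the exact test with a 1-kb window (adjusted p = 0.122), the nearest gene (0.191), equal numbers of strongest peaks (0.194) and gene bodies alone (0.671), and against random lists matched on non-coding bases (0.0860). The 1 SEP3wt-only and 5 SEP3tet-only members showed no difference from all line-only targets (exact test, odds ratio 1.35, adjusted p = 0.927), too few to reveal a lean to SEP3tet. Floral meristem and carpel genes did not pass in either line, with 6 of 25 targets each (adjusted p = 0.218 in SEP3wt and 0.843 in SEP3tet, exact test). SPT of this list, named after its values were seen, was a target in neither line under the 3-kb window. Yet SPT was the nearest gene of the SEP3tet peak with the highest fold, 11.9 (chromosome 4, 17408373 to 17409839). A SEP3wt peak that overlapped it had a fold of 10.4. CLV1, SUP, IND, ALC and ETT were targets in both lines, HEC1 in SEP3wt only and RPL in SEP3tet only (fold 5.19; chromosome 5, 392912 to 393159).

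Root regulators, a comparison list, had 6 of 20 targets in each line and did not pass (adjusted p = 0.0849 in SEP3wt and 0.494 in SEP3tet, exact test), but passed in SEP3wt with only summits outside every gene (5 targets, adjusted p = 0.0384). SCR, GL2, BRN1, AGL21 and AGL16 were targets in both lines, WER in SEP3wt only and ANR1 in SEP3tet only. Housekeeping and photosynthesis genes, listed for comparison, had 9 of 20 targets in each line and passed in SEP3wt (odds ratio 5.17, adjusted p = 0.00222) but not in SEP3tet (odds ratio 3.05, adjusted p = 0.0590, Fisher's exact test); the test between SEP3wt-only and SEP3tet-only targets gave an adjusted p of 0.927. In SEP3wt, 8 of these genes had a summit in a gene body and 0 had one that lay outside every gene. RBCS1A, RBCS3B, LHCB1.1, LHCB1.3 and ACT8 were targets in both lines, LHCB2.1 and RCA in SEP3wt only, and ACT7 in SEP3tet only. LHCB1.1 is the gene named CAB2 above. Its strongest peak in each line was also that of LHCB1.3 and had its summit in the body of LHCB1.3. The 50 genes with an RPL or RPS symbol and a number, a family meant for ribosomal proteins, had 5 targets in SEP3wt and 7 in SEP3tet (adjusted p = 0.580 and 0.390, exact test). This symbol rule also took in the disease resistance genes RPS2, a target in both lines, and RPS6, a target in SEP3tet only, which are named after their values were seen.

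Among the symbol families, TCP, SPL and SAUR genes were over-represented in both lines and GRF genes passed in SEP3tet only. Some TCP, GRF and SPL genes are also in the organ growth and polarity list, and some SPL genes in the flowering list. The calls of these lists and families are therefore not independent. TCP genes, which control cell proliferation, had 9 of 22 targets in SEP3wt (odds ratio 4.37, adjusted p = 0.00474) and 13 of 22 in SEP3tet (odds ratio 5.38, adjusted p = 0.000504, exact test). SPL genes, which include regulators of phase change and flowering, had 9 of 18 (odds ratio 6.31, adjusted p = 0.000969) and 12 of 18 (odds ratio 7.45, adjusted p = 0.000270, exact test). GRF genes, which promote organ growth, had 3 of 9 in SEP3wt (odds ratio 3.15, adjusted p = 0.187) and 8 of 9 in SEP3tet (odds ratio 29.8, adjusted p = 0.000226, Fisher's exact test). With equal numbers of strongest peaks, GRF genes in SEP3tet had 6 of 9 (odds ratio 11.7, adjusted p = 0.00211, exact test). Their 0 SEP3wt-only and 5 SEP3tet-only members showed no difference from all line-only targets (exact test, adjusted p = 1.00), again too few to reveal a lean to SEP3tet. The auxin-induced SAUR genes had 26 of 80 in SEP3wt and 33 of 80 in SEP3tet (odds ratios 3.05 and 2.62, adjusted p = 0.000193 and 0.000277, exact test), and neighbouring copies can share a summit. With gene bodies alone, TCP and SAUR genes passed in neither line and GRF genes not in SEP3tet (adjusted p from 0.230 to 0.925, exact test).

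The Aux/IAA, ARF, WRKY, MYB, LBD, WOX, BLH or KNAT, CKX and GASA families passed in neither line with the 3-kb window, with adjusted p from 0.0785 (WRKY) to 1.00 (WOX and GASA) in SEP3wt and from 0.0667 (MYB) to 0.562 (WOX) in SEP3tet. The symbol rule counted ARF19, a target in SEP3tet only, in both the Aux/IAA and the ARF family. The results of these families are therefore not independent, and ARF19 is named after its value was seen. Several families passed under other rules. Counting only the nearest gene, Aux/IAA, WRKY and MYB genes passed in both lines (adjusted p at most 0.0327) and ARF and BLH or KNAT genes in SEP3tet (0.0496 and 0.0163). WRKY genes passed with gene bodies alone (0.0271 in SEP3wt and 0.00390 in SEP3tet), and MYB and BLH or KNAT genes in SEP3tet with summits outside genes (0.00413 each).

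**Figure D3:**
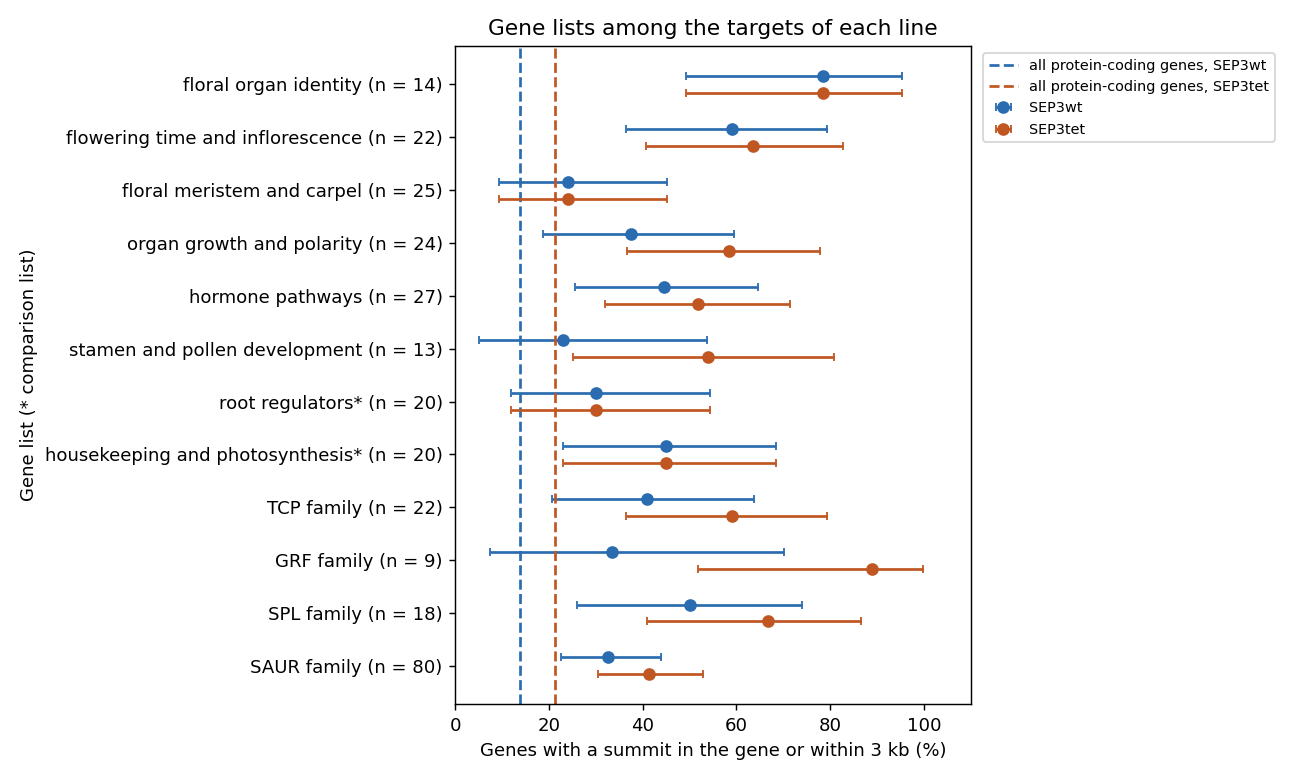
Share of genes (%) with a summit in the gene or within 3 kb, for the 8 fixed lists and 4 symbol families, in SEP3wt (blue) and SEP3tet (orange); points are shares, bars exact 95% intervals over genes, and dashed lines the share among all protein-coding genes (13.7% and 21.2%). Floral organ identity genes stand at 78.6% in both lines and the GRF family at 33.3% in SEP3wt and 88.9% in SEP3tet.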

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

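No paired analysis was possible because the data were 1 peak list per line with no values per replicate, and for the same reason no replicate was left out. Of the planned results, CArG boxes, CArG box pairs and other motifs were not run, nor was the order with promoters before exons. Counting every summit apart changed nothing, since no peaks of a list overlapped. Sharing within 1 kb, gene bodies alone, summits outside genes, and the gene-body difference at −log10 q of at least 5 or with sharing within 1 kb were chosen after seeing the data. Library sizes are unknown, so whether depth limits the SEP3wt list could not be tested. In every setting run SEP3tet kept more peaks than SEP3wt, except with equal numbers of peaks. Leaving out gene-poor windows gave a shared share of 84.8% of SEP3wt and 53.4% of SEP3tet peaks.

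At −log10 q of at least 5 the lists held 1218 (SEP3wt) and 2245 (SEP3tet) peaks, and at 10, 626 and 1114. In that order, the shared share was 86.9% and 47.2% at 5, 82.9% and 46.7% at 10, 66.5% and 41.1% with reciprocal overlap, 71.2% and 44.0% for summits within 100 bp, 89.4% and 58.8% within 1 kb, and 68.5% and 67.5% with equal numbers of strongest peaks. Summits in gene bodies were 40.1% and 32.6% at 10, where the gene-body difference of 27.3 points lost its call (exact p = 0.205) with fewer peaks by construction. It was 28.1 points with peak centres, 23.8 at 5 and 24.1 with sharing within 1 kb (p at most 0.000716).

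Target genes, as SEP3wt, SEP3tet and both, were 2137, 3387 and 1888 with 1 kb, 1833, 2883 and 1620 with the nearest gene, and 1262, 2131 and 1049 at −log10 q of at least 10. SEP3wt-only targets were 213 with the nearest gene and 213 at 10, and 868 with equal numbers of peaks. SEP3tet-only targets were 1499 with 1 kb, 1263 with the nearest gene, 1082 at 10 and 1125 with equal numbers. These follow from narrower windows or fewer peaks by construction.

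Lists over-represented in SEP3tet rose from 9 to 14 with the nearest gene and fell to 5 with gene bodies alone. Of 17 calls of a list in a line, 15 were kept with 1 kb, 16 with the nearest gene, 16 with matched lists, 16 with equal numbers of peaks, 16 with summits outside genes and 8 with gene bodies alone. Some odds ratios changed sides of 1; the cause was not tested. With gene bodies alone they were 0 for meristem and carpel and GASA genes in both lines and for stamen, GRF and BLH or KNAT genes in SEP3wt, and 0.959 for ARF genes in SEP3tet. With summits outside genes they were 0 for housekeeping and photosynthesis genes in SEP3wt (the only call among all these), 0.907 for WOX and 1.03 for RPL or RPS genes in SEP3wt. With 1 kb they were 0.617 for meristem and carpel genes in SEP3tet and 0 for BLH or KNAT and GASA genes in SEP3wt, and with the nearest gene 0.822 and 0 for these families in SEP3wt. With equal numbers of peaks they were 0.833 for Aux/IAA and 0.972 for GASA genes in SEP3tet, and ratios to matched lists were 0.936 for WOX and 0.963 for GASA genes in SEP3wt. Housekeeping genes passed in SEP3tet with 1 kb (exact test, adjusted p = 0.0211), the nearest gene (0.00691) and gene bodies alone (0.00844). Aux/IAA genes also passed in SEP3tet and WRKY genes in SEP3wt with 1 kb (0.0331 and 0.00931), and BLH or KNAT genes in SEP3tet with equal numbers of peaks (0.0279, exact test).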

Other observations

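The families and comparisons described in this part, and the tests on photosynthesis genes and on depth, were chosen only after the peaks were seen; the tests on peak strength, side peaks, threshold and non-coding DNA were set before their results were seen. The jasmonate signalling repressors of the JAZ family had 7 of 12 targets in SEP3wt and 6 of 12 in SEP3tet (odds ratios 8.84 and 3.72; Fisher's exact test, adjusted over 4 added families and 2 lines, p = 0.000756 and 0.0343), with summits in the bodies of 5 and 4 genes. ERF genes, ethylene-response transcription factors, had 12 and 16 of 26 (odds ratios 5.41 and 5.97, adjusted p = 0.000170 and 3.78e-05, exact test). Calmodulin-like CML genes had 5 of 14 in each line (adjusted p = 0.0377 and 0.192, exact test). Nuclear photosynthesis genes had 22 of 52 in SEP3wt and 18 in SEP3tet (odds ratios 4.64 and 1.97, adjusted p = 3.21e-06 and 0.0343, exact test). Of these, 8 were SEP3wt-only and 4 SEP3tet-only targets, and the family was picked after such genes were seen among the SEP3wt-only peaks. With gene bodies alone all 4 added families passed in both lines (exact test, adjusted p at most 0.0231). With only summits outside every gene none of them passed in either line (exact test, adjusted p of 0.0684 or more). Whether their gene-body summits hold background over transcribed genes was not tested. The widest peak of each list had its summit 1 to 3 kb from AGC1.7 (chromosome 1, 29804345 to 29809568 in SEP3wt), and among the next widest in both were peaks with the summit in LOX3, a jasmonate synthesis gene (chromosome 1, 5977201 to 5981530 in SEP3wt), CIPK9 and ACA1.

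Of 326 microRNA genes, 11 had a summit within 1 kb in SEP3wt, 26 in SEP3tet and 9 in both. Of 27444 protein-coding genes, 2137 in SEP3wt and 3387 in SEP3tet had one within 1 kb, a larger share in each line. The SEP3tet list also held more peaks. MIR159a, MIR168a, MIR168b and MIR172b were among the 9. MIR172b belongs to the family that targets AP2-like genes, and AP2, TOE1, TOE3, SMZ and SNZ were targets in both lines, with folds of 4.60 (TOE1), 5.66 (SMZ) and 8.81 (SNZ) in SEP3wt. In both lines the strongest SMZ and SNZ peaks lay nearest to the neighbouring genes TON1A and AT2G39260. MIR396b, whose family targets GRF genes, MIR160a, MIR390a and MIR166b, MIR166d and MIR166g had a summit in SEP3tet only, as did MIR156i, while MIR156b had a summit in SEP3wt only. These microRNA genes, with TOE1, SMZ and SNZ, were named after their values were seen. No test of the microRNA numbers was made.

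The SEP3wt-only peaks lay in gene bodies more often than the SEP3tet-only peaks, by 28.8 percentage points. Weak peaks near the threshold as the whole explanation of this difference were argued against. Among line-only peaks of −log10 q of at least 5 the difference was 23.8 points (29 of 52 against 232 of 726, Fisher's exact p = 0.000716). The planned threshold of 10 gave 27.3 points with fewer peaks (Fisher's exact p = 0.205) and cannot decide. At 5 the SEP3wt-only share was 55.8%, near the 54.1% of genome bases, so its excess over the genome was not seen there. The gene-body peaks at 5 had a median width of 614 bp in SEP3wt-only and 253.5 bp in SEP3tet-only. Background over abundantly transcribed genes may account for a part and stays open: 5.29% of SEP3wt-only gene-body summits lay in nuclear photosynthesis genes against 0.157% of SEP3tet-only ones, but this family was picked because such genes were seen among the SEP3wt-only peaks, so the shares decide nothing. Photosynthesis genes were not the whole pattern, since without them the difference was 27.6 points (exact p = 4.41e-20). Only 12 SEP3wt-only and 1 SEP3tet-only gene-body summits were left out. The difference could therefore hardly change, and the p-value adds nothing to these counts. Other transcribed genes and a real difference between the proteins stay open, as the mock signal was not analysed here. The unequal lengths of the lists stay open too. Line-only peaks were 15.3% of the SEP3wt list and 46.7% of the SEP3tet list. The gene-body contrast was not repeated with equal numbers of peaks.

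The SEP3tet list held more peaks than the SEP3wt list. Side peaks of shared regions were argued against as the cause, with 11.7% of SEP3tet-only peaks within 1 kb of a SEP3wt peak. The ratio of peak numbers at −log10 q of at least 10 was 1.78, so the excess was not confined to peaks just past the threshold. That ratio counts shared and line-only peaks together, so it cannot decide whether the SEP3tet-only peaks are mostly such extra peaks. Their median −log10 q was 4.67, against 9.98 for shared SEP3tet peaks. Deeper or better enriched SEP3tet libraries may give the same picture, as 92.8% of the highest of 5 parts of SEP3tet peaks were shared and SEP3tet-only peaks were weaker. Without library sizes or lists per replicate, this cannot be told apart from wider binding by SEP3tet, which stays open and untested. The level of SEP3 protein and the make-up of the tissue in each line were not examined here. Differences between the lines in these cannot be told apart from an effect of tetramerization either.

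Floral organ identity and flowering genes were over-represented among targets of both lines. More non-coding DNA around these genes, which gives a summit more room, was argued against as the cause: among 10000 lists matched on non-coding bases, the largest one-sided p for reaching the observed number, over both lists and both lines, was 0.00020 (flowering genes in SEP3tet). Background over transcribed genes was not tested for these lists and stays open. The housekeeping and photosynthesis comparison list also passed in SEP3wt (odds ratio 5.17, Fisher's exact test, adjusted p = 0.00222). With only summits outside every gene it had 0 targets in SEP3wt, against 9 organ identity and 12 flowering genes. Another candidate explanation that stays is binding by SEP3 near these genes in both lines. It is a hypothesis found and tested on the same lists, and the sequences under the peaks were not analysed here.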
